A study of Mus musculus with 12 samples.

How the data were processed

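Total RNA of sorted GFP-positive mouse bone marrow cells was labelled with biotin and hybridised to Affymetrix mouse arrays, 12 in all, with 3 for each of the empty vector, IDH1wt, IDH1mut and R-2HG groups. Groups were taken from the samples' titles, source names and construct fields. The description field of the R-2HG samples names another vector and was not followed.

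The deposited values are log2 expression values made with RMA (version not given), per the submitters' processing notes. The deposited table holds 32533 probe sets for the 12 arrays, from -6.48 to 4.93. It is centred per probe set: at most 7 of the 12 values of any probe set lie above 0 and at most 7 below, and 83.6% of probe sets hold an exact 0. These limits fit a median over 15 arrays, of which 12 were analysed here. The median of every array is 0. The centring, its exact reference and the absolute level are not given in the sources used here. Affymetrix control probe sets are not in the table used here, so RNA quality was not checked from them, and no scan date or batch was given.

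Probe sets were named through the platform annotation. A single gene symbol was listed for 28805 probe sets, several for 757 and none for 2971, and only the first kind was used. Of these, 28674 had their Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. The planned rule took for each gene the probe set with the highest mean level. Centred values carry no level, so the mean of all probe sets of a gene, planned as an alternative, was used instead, which gave 15858 genes, 8510 of them with 1 probe set. The literal rule was run as an alternative. The planned filter on mean level was not run for the same reason, and a filter on the SD took its place.

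Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend, 8 residual and 3.96 prior degrees of freedom), with 1 coefficient per group over all 12 arrays. Tests were two-sided with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors given with log2 fold changes are SEs of the moderated fit with n = 3 per group. An F test covered the 3 contrasts against empty vector. The 34 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. With the estimated correlation 0 of 34 lists passed in any of the 5 comparisons, and by fry 11, 16, 5, 3 and 18 passed, in the order IDH1mut and R-2HG against empty vector, IDH1mut against IDH1wt, IDH1wt against empty vector and IDH1mut against R-2HG. Fry asks whether the genes of a list move one way and does not compare them with other genes. Counts of called list members stand against the share of all genes called, 22.6%, 40.8%, 15.7%, 1.35% and 36% in the same order. Similarity of contrasts was measured across genes and set beside the mean of 100 simulations without an effect, with genes drawn independently.

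Genes are named by a rule fixed before the data were examined: in each comparison the 12 largest changes in each direction among genes past the threshold whose groups do not overlap, clone and predicted names left out, the 4 members with the smallest p of each list that passes and 2 of each other list, and a short set tied to IDH1 and HoxA9. A gene named in one comparison may be given in another. Not every gene that the rule names is reported here. Genes outside the rule are marked as such where they appear.

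The fits were tested on simulated data with known changes in 200 of the 15858 genes. For IDH1mut against empty vector, 58.2%, 95.5% and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, and for R-2HG against empty vector 56.7%, 94% and 100%. Among unchanged genes 0.083% and 0.057% were called. The simulation gave each gene the same SD in all groups and independent normal noise. It does not carry the distance of R-2HG replicate 3 from replicates 1 and 2, so the R-2HG rates may not hold for the real arrays. Figures were drawn with matplotlib 3.10.9.

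Alternatives were a second quantile normalization, run on the centred values, and centring of each array (without effect, as all array medians are 0). Single probe sets, eBayes with trend, array weights and a replicate block were also run. So were a fold change minimum of 1.5, fits of 6 arrays, and each array left out in turn. Chosen after seeing the data were the probe set with the highest mean of the centred values, the probe set with the highest SD, the SD filter at the 30th percentile, and leaving out R-2HG replicates 1 and 2 together.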

Results

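Gene expression was measured on 12 mouse Affymetrix arrays, 3 in each of 4 groups. All cells descended from C57BL/6 bone marrow immortalised with HoxA9, a homeobox transcription factor that keeps myeloid progenitors dividing. The cells received a retroviral empty vector, wild-type isocitrate dehydrogenase 1 (IDH1wt) or mutant IDH1 (IDH1mut), and were then transplanted into irradiated mice. IDH1 is a metabolic enzyme whose cancer-associated mutants produce R-2-hydroxyglutarate (R-2HG). The R-2HG group consisted of recipients of empty vector cells that were given R-2HG at 1 mg per day for 4 weeks. RNA came from GFP-positive marrow cells sorted after 4 weeks. One label field of the R-2HG samples names the IDH1mut vector, whereas their titles, source names and construct fields and the series design name the empty vector, which was followed here. The labels do not say that replicates came from separate mice, so the p-values measure only the spread between these samples, which may be technical. The values are log2 values centred per probe set, so they give differences between arrays and no absolute level, and the number of arrays limits their precision.

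Replicates lay closer to each other than to other groups in most pairs. The SD of the difference between 2 arrays over all probe sets ran from 0.178 to 0.362 within groups and from 0.294 to 0.555 between groups. The first principal component held 45.9% of the variance. R-2HG replicates 1 and 2 lay at 43.04 and 44.61 on it, R-2HG replicate 3 at 13.42, and no array of another group above 0.49. The F test over the 4 groups called 8651 of 15858 genes at an adjusted p under 0.05.

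**Figure D1:**
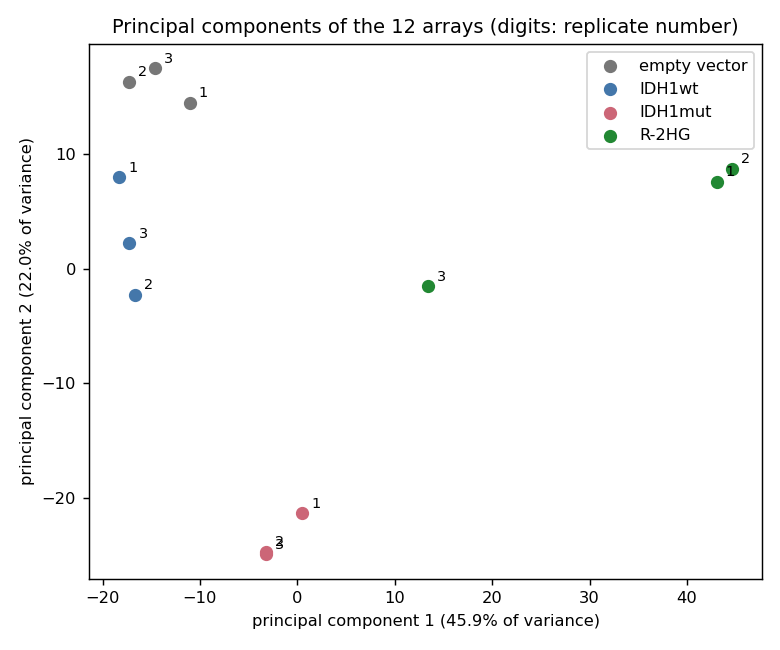
First and second principal components of the 12 arrays, with 1 point per array, coloured by group and numbered by replicate. R-2HG replicate 3 sits at 13.42 on the first component, between R-2HG replicates 1 and 2 at 43.04 and 44.61 and the 9 other arrays at 0.49 or below.

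The genes that bear on the constructs and on 2-hydroxyglutarate were looked at first. Idh1 did not differ in any comparison, with log2 fold changes from -0.19 to 0.12 and a lowest adjusted p of 0.211, but with array weights it passed for R-2HG against empty vector (0.21, adjusted p = 0.0387) and for IDH1mut against R-2HG (-0.29, adjusted p = 0.0199), the latter also without R-2HG replicate 3 (adjusted p = 0.0332). Its probe sets may not detect the introduced sequence, so they do not check the labels. Hoxa9 was lower in IDH1mut than in IDH1wt (log2 fold change -0.54 ± 0.08 (SE, n = 3 per group), adjusted p = 0.00135) and than in R-2HG (-0.32 ± 0.08, adjusted p = 0.0126), the latter not at 1 probe set (-0.15, adjusted p = 0.244) or without R-2HG replicates 1 and 2 (-0.33, adjusted p = 0.164). Against empty vector Hoxa9 stood at -0.24 ± 0.08 (adjusted p = 0.0515) and passed with array weights (-0.26, adjusted p = 0.0142), after quantile normalization (-0.29, adjusted p = 0.0386), with a trend in eBayes (adjusted p = 0.0424) and without IDH1mut replicate 3 (-0.34, adjusted p = 0.00757). Whether the Hoxa9 probe sets detect the introduced HoxA9 is not known here. Idh2, the mitochondrial relative of Idh1, fell in R-2HG (-0.82 ± 0.09, adjusted p = 7.97e-05) and in IDH1mut (-0.41 ± 0.09, adjusted p = 0.00592) against empty vector, the latter not at 1 of its probe sets (-0.16, adjusted p = 0.408). Dnmt3a, a DNA methyltransferase, fell in R-2HG (-0.53 ± 0.09, adjusted p = 0.000971) and was at -0.03 ± 0.09 in IDH1mut (adjusted p = 0.832). The call in R-2HG was lost without R-2HG replicates 1 and 2 (-0.39, adjusted p = 0.052) and at 1 probe set (-0.03, adjusted p = 0.85). D2hgdh, which oxidises 2-hydroxyglutarate, Tet2, Cdkn1a and Cdkn2b passed in none of the 5 comparisons. At single probe sets D2hgdh passed for R-2HG against empty vector (-0.30, adjusted p = 0.0348) and for IDH1mut against R-2HG (0.46, adjusted p = 0.00655), and Cdkn1a for IDH1mut against empty vector (-0.38, adjusted p = 0.0214). D2hgdh also passed for IDH1mut against R-2HG with array weights (adjusted p = 0.0268), without IDH1mut replicate 1 (adjusted p = 0.0429) and without R-2HG replicate 3 (adjusted p = 0.0445).

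The effect of mutant IDH1 was first measured against the empty vector. Genes of late neutrophil maturation rose and genes of the early granules fell. Of 21 measured secondary granule and mature neutrophil genes, 15 were higher and 0 lower (15 adjusted over the list alone), with a median log2 fold change of 0.52. They included Mmp8, the neutrophil collagenase (2.15 ± 0.17), Ltf, which encodes lactoferrin (0.70 ± 0.08), and Padi4 (0.89 ± 0.10). Of 9 primary granule genes, 8 were lower and 0 higher (8 adjusted over the list alone), with a median of -0.81, among them the elastase gene Elane (-1.10 ± 0.13) and the cathepsin G gene Ctsg (-0.94 ± 0.09). Type I interferon response genes rose, 16 higher and 2 lower of 29 (17 and 3 adjusted over the list alone), with Rsad2 at 1.32 ± 0.12 and Ifit3 at 1.62 ± 0.19. The adjusted p-values of these 3 lists were 1.21e-12, 2.62e-06 and 4.46e-06 by camera. They rose to adjusted p = 0.0968, 0.11 and 0.538 with an estimated correlation.

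Single genes moved further. Sall2, a zinc finger gene, was the most increased (4.73 ± 0.17, adjusted p = 3.34e-08) and was high in the IDH1mut arrays alone. Bex1 rose by 3.42 ± 0.51, Ovgp1, which encodes a chitinase-like glycoprotein, by 2.49 ± 0.11, Olfm4, a gene of a neutrophil subset, by 2.18 ± 0.18, and Mecom, a stem cell transcription factor, by 1.51 ± 0.13. Cdkn2a, the locus of the p16 and p19 growth inhibitors, fell by 2.37 ± 0.21 (adjusted p = 2.55e-05). Ptprg changed by -3.08 ± 0.16 and As3mt, an arsenic methyltransferase gene, by -2.41 ± 0.25. The heat shock gene Hspa1a (-4.27 ± 0.32) and the immediate early genes Egr1 (-2.20 ± 0.19) and Jun (-1.98 ± 0.17) were also lower. Hspa1a and Hspa1b are near-identical copies, so their probe sets cannot be told apart with certainty. Bex1, Hspa1a, Egr1 and Ptprg changed in IDH1wt against empty vector too, so they do not follow the mutation alone. For Jun all 3 empty vector arrays lay above every other array, those of IDH1wt included. Against IDH1wt the changes of Ovgp1 (1.85), Olfm4 (1.345), Cdkn2a (-1.64) and As3mt (-2.19) were smaller than against empty vector. Those of Sall2 and Mecom were about as large. For Mecom, 1 probe set did not change (0.10, adjusted p = 0.716), nor did it against IDH1wt (adjusted p = 0.729).

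Other lists passed as well. Erythroid genes rose with a median of 1.16, although only 4 of 18 were called, and their median per array ran from -0.86 to -0.66 in empty vector and from 0.20 to 0.41 in IDH1mut. Oxidative phosphorylation genes fell, 12 lower and 2 higher of 33, as did cytosolic ribosomal protein genes (10 lower and 3 higher of 28) and MYC and ribosome biogenesis genes (10 lower and 1 higher of 40). NF-kB and inflammatory genes (10 higher, 2 lower of 27), p53 target genes (8 higher, 2 lower of 26), megakaryocyte and platelet genes (3 higher, 0 lower of 13) and T and NK cell genes (3 higher, 0 lower of 18) rose. The 7 lists other than the erythroid one gave an adjusted p between 0.181 for p53 target genes and 0.917 for MYC genes with an estimated correlation, and erythroid genes gave 0.897. Of 20 other settings of the fit, MYC genes lost their call in 3, NF-kB and ribosomal protein genes in 2 each, and megakaryocyte genes and T and NK cell genes in 1 each.

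In all, limma called 3579 of 15858 genes, 1662 higher and 1917 lower, of which 162 and 70 changed at least 2-fold. The arrays of the 2 groups did not overlap in 41.1% of all genes, where chance gives 10%. The count with a fold change of at least 1.5 was 930.

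**Figure D2:**
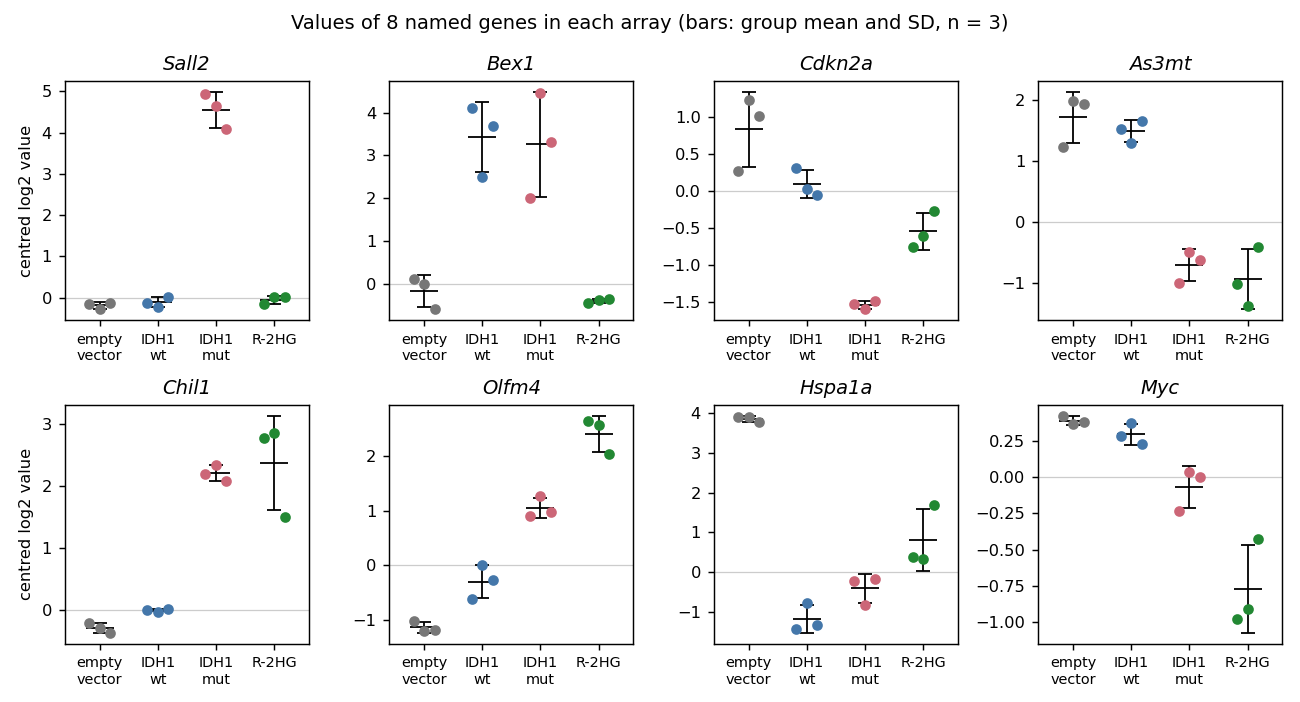
Centred log2 values of 8 named genes in each of the 12 arrays, with points for arrays and bars for the group mean and SD (n = 3). Sall2 is high in the IDH1mut arrays alone, As3mt is low in the IDH1mut and R-2HG arrays, and Hspa1a is high in the empty vector arrays.

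Treatment of recipients with R-2HG was compared with the same vector cells in untreated recipients. Genes of ribosome production and growth fell. Of 40 MYC and ribosome biogenesis genes, 34 were lower and 0 higher (35 and 0 adjusted over the list alone), with a median of -0.59. Myc itself, a growth-promoting transcription factor, changed by -1.16 ± 0.13, Wdr12 by -1.06 ± 0.14 and Pes1 by -0.75 ± 0.09. Oxidative phosphorylation genes (24 lower, 0 higher of 33), TCA cycle, IDH and glutamate metabolism genes (18 lower, 0 higher of 34) and cytosolic ribosomal protein genes (17 lower, 2 higher of 28) also fell. So did DNA replication and G1/S genes (23 lower, 4 higher of 38), with Cdk4 at -0.99 ± 0.11 and Mcm2 at -0.57 ± 0.07, and mitosis and G2/M genes (16 lower, 0 higher of 36). The camera adjusted p-values of these 6 lists ran from 1.19e-11 to 0.00324. They lay between 0.619 and 0.707 with an estimated correlation.

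Neutrophil granule genes changed as well. Of 21 secondary granule and mature neutrophil genes 14 were higher and 0 lower (14 adjusted over the list alone), with a median of 0.37, Padi4 at 1.07 ± 0.10 and Mmp9 at 0.71 ± 0.10. Of 9 primary granule genes 8 were lower and 1 higher (8 and 1 adjusted over the list alone), with a median of -0.53, Ms4a3 at -0.89 ± 0.12 and Ctsg at -0.62 ± 0.09. Type I interferon response genes rose, 16 higher and 2 lower of 29, with Ifit3 at 1.22 ± 0.19. None of the 3 lists passed with an estimated correlation (adjusted p = 0.589, 0.619 and 0.619).

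Stem and progenitor genes fell, 11 lower and 1 higher of 22, among them Cd34 (-0.97 ± 0.13) and Cd27 (-1.54 ± 0.20). Cholesterol and fatty acid synthesis genes (12 lower, 2 higher of 27) and amino acid and ER stress genes (17 lower, 5 higher of 35) fell too. These 3 lists had an adjusted p of 0.674, 0.619 and 0.659 with an estimated correlation. Without R-2HG replicates 1 and 2 the stem and progenitor list and the cholesterol list no longer passed. Of 21 other settings, the amino acid and ER stress list lost its call in 4 and the cytosolic ribosomal protein list in 1. Markers of other cell types also set R-2HG replicates 1 and 2 apart, but replicate 3 lay below empty vector only for B cell genes. The median of 16 mast cell, basophil and eosinophil genes was -1.12, -1.13 and 0.05 in R-2HG replicates 1, 2 and 3. In empty vector it ran from -0.002 to 0.048. That of 18 erythroid genes was -1.55, -1.88 and 0, against -0.86 to -0.66 in empty vector. That of 15 dendritic cell genes was -0.71, -0.63 and 0.28, against 0.059 to 0.255. That of 19 B cell genes was -0.63, -0.50 and -0.15, against 0 to 1.038. None of these 4 lists passed its test (adjusted p = 0.22, 0.519, 0.0785 and 0.0697).

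The genes that rose most were Olfm4 (3.54 ± 0.18, adjusted p = 1.05e-06), Chil1 (2.67 ± 0.26), Slfn4 (2.48 ± 0.15), Slc16a9 (2.46 ± 0.36) and Fmnl2 (2.06 ± 0.25). Among those that fell most were Cst7 (-4.33 ± 0.87), Dleu7 (-4.16 ± 0.41), Tctex1d1 (-4.16 ± 0.19) and the eosinophil granule gene Prg2 (-4.01 ± 0.79). Cst7 stood at -4.77, -5.05 and -0.41 in R-2HG replicates 1, 2 and 3. Cdkn2a changed by -1.38 ± 0.21 (adjusted p = 0.00043), As3mt by -2.65 ± 0.25 and Ptprg by -2.99 ± 0.16. Sall2 (0.14 ± 0.17, adjusted p = 0.531) and Bex1 (-0.23 ± 0.51, adjusted p = 0.741) did not differ from empty vector.

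Limma called 6471 genes, 2619 higher and 3852 lower, of which 57 and 290 changed at least 2-fold, and 53.5% of all genes had groups that did not overlap. The count was 1627 with a fold change of at least 1.5, and 1824 without R-2HG replicates 1 and 2, where the lone remaining array is assumed to vary like the other groups.

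Mutant IDH1 was then set against wild-type IDH1, which also carries an IDH1 construct. The level of the constructs was not measured here. Secondary granule and mature neutrophil genes rose again, 17 higher and 0 lower of 21 (18 and 0 adjusted over the list alone), with a median of 0.52, Mmp8 at 1.51 ± 0.17 and Anxa1 at 0.89 ± 0.10. Primary granule genes fell, 7 lower and 1 higher of 9 (8 and 1 adjusted over the list alone), with Mpo, the myeloperoxidase gene, at -0.67 ± 0.08 and Ctsg at -0.85 ± 0.09. Their camera adjusted p-values were 1.31e-14 and 1.31e-06, and with an estimated correlation the adjusted p was 0.0633 and 0.0969. Monocyte and macrophage genes fell, 8 lower and 0 higher of 23, with Irf8, a monocyte lineage factor, at -0.86 ± 0.15 and Cd14 at -0.88 ± 0.18. Type I interferon response genes (11 higher, 1 lower of 29) and T and NK cell genes (4 higher, 0 lower of 18) rose, the latter with the T cell receptor chain gene Cd247 at 1.37 ± 0.16. With an estimated correlation the adjusted p was 0.723 for the monocyte and interferon lists and 0.449 for the T and NK cell list.

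B cell genes rose, 4 higher and 0 lower of 19, led by Vpreb1 (2.48 ± 0.44), a surrogate light chain gene of early B cells, and Dntt (2.06 ± 0.35). This list no longer passed without IDH1wt replicate 1 or without IDH1mut replicate 3. Erythroid genes passed as a list with a median of 0.61 and 0 of 18 genes called, and did not pass without IDH1wt replicate 1. Sorting, dissociation and heat shock genes rose, 4 higher and 2 lower of 23. Oxidative phosphorylation genes (5 lower, 1 higher of 33), cytosolic ribosomal protein genes (7 lower, 2 higher of 28), MYC and ribosome biogenesis genes (3 lower, 1 higher of 40), dendritic cell genes (3 lower, 0 higher of 15) and mast cell, basophil and eosinophil genes (3 lower, 0 higher of 16) fell. Each of these 8 lists had an adjusted p of 0.723 with an estimated correlation. By fry only the ribosomal protein list passed (adjusted p = 0.0489), and the others lay between 0.176 and 0.271. Limma called 15.7% of all genes in this comparison, so small counts alone do not mark a list, as for MYC genes. Of 20 other settings, the dendritic list lost its call in 5, the mast cell list in 3, the oxidative phosphorylation and sorting lists in 2 each and the ribosomal protein list in 1.

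Sall2 (4.66 ± 0.17, adjusted p = 4e-08), Chil1 (2.21 ± 0.26), Fmnl2 (1.96 ± 0.25), Ovgp1 (1.85 ± 0.11) and Mecom (1.58 ± 0.13) were among the increased genes. As3mt (-2.19 ± 0.25), Perp (-1.93 ± 0.20) and Cdkn2a (-1.64 ± 0.21, adjusted p = 0.00045) were among the decreased ones. Perp was raised in IDH1wt over empty vector, as given below, so its decrease here is no fall below empty vector. Limma called 2484 genes, 1328 higher and 1156 lower, of which 83 and 54 changed at least 2-fold. The groups did not overlap in 32.7% of all genes. The count was 1568 without IDH1wt replicate 3, 1636 without IDH1mut replicate 2 and 596 with a fold change of at least 1.5.

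Wild-type IDH1 differed from the empty vector in far fewer genes. Heat shock and immediate early genes were among the largest decreases. Of 23 sorting, dissociation and heat shock genes, 8 were lower and 0 higher (10 and 0 adjusted over the list alone), with Hspa1a at -5.03 ± 0.32, Hspa1b at -5.07 ± 0.37, Fosb at -2.36 ± 0.28, Egr1 at -2.14 ± 0.19 and Fos at -1.68 ± 0.26. The camera adjusted p was 5.01e-07, and with an estimated correlation the adjusted p was 0.651. Histone genes fell, 2 lower and 0 higher of 9. Type I interferon response genes (1 higher, 0 lower of 29), cholesterol and fatty acid synthesis genes (1 higher, 0 lower of 27), erythroid genes and monocyte and macrophage genes (0 called of 18 and of 23) passed upwards. The adjusted p of these 5 lists lay between 0.651 and 0.802 with an estimated correlation. Of 20 other settings, histone genes lost their call in 9, cholesterol and monocyte genes in 4 each, erythroid genes in 3 and interferon genes in 2.

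Bex1 (3.59 ± 0.51), Cela1, an elastase family gene (3.15 ± 0.34), Pls3 (2.26 ± 0.21) and Perp (2.16 ± 0.20) rose, and Ptprg fell by 3.12 ± 0.16. The secondary granule list had a median of -0.02 and the primary granule list one of -0.09, and neither passed. Limma called 214 genes, 125 higher and 89 lower, which is 1.35% of those tested, and 23.8% of all genes had groups that did not overlap. This count depended on single arrays and on the setting. It was 84 without empty vector replicate 3, 89 without empty vector replicate 2, 86 and 123 without IDH1wt replicates 3 and 2, 375 without R-2HG replicate 3 and 1388 with array weights. R-2HG replicate 3 is in neither group, so leaving it out acts only through the estimate of spread shared by all arrays. In the fit of only the 6 arrays of the 2 groups the count was 283.

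The effects of mutant IDH1 and of R-2HG were compared in a pair of contrasts that share no array, IDH1mut against IDH1wt and R-2HG against empty vector. Across genes, which are not independent replicates, their log2 fold changes correlated with Pearson's r = 0.439. Simulated groups without an effect gave a mean r = 0.002. The 2 contrasts share no simulated group, which puts that mean near 0 by design. Genes were also drawn independently, so the simulations are no yardstick for the spread of r in arrays whose genes vary together. Both contrasts called 641 genes higher and 801 lower, against 219 and 281 for independent lists, and 56 in opposite directions, against 513. The calls of both come from the same fit and share each gene's estimate of spread, so the counts for independent lists are no exact yardstick. That estimate does not set the direction of a call. In 1356 genes called alike the groups overlapped in neither contrast. They included Chil1, As3mt, Fmnl2, Dnah6 (1.96 ± 0.29 and 1.87 ± 0.29), Hnmt, a histamine methyltransferase gene (-1.88 ± 0.31 and -2.79 ± 0.31), Olfm4 and Cdkn2a.

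With the shared empty vector control, IDH1mut and R-2HG changes correlated with r = 0.506, and unchanged groups simulated against those controls gave r = 0.349. The simulated r is scaled by noise alone, so it is not the part of 0.506 that comes from the controls. The covariance was 0.0679 against a simulated 0.00612, which left 0.0618. Both contrasts called 804 genes higher and 1400 lower, against 274 and 466 for independent lists. The 3 control arrays cannot be split into separate sets of at least 2. Part of the excess of calls may thus come from the shared controls, or from the estimate of spread that both contrasts share.

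**Figure D3:**
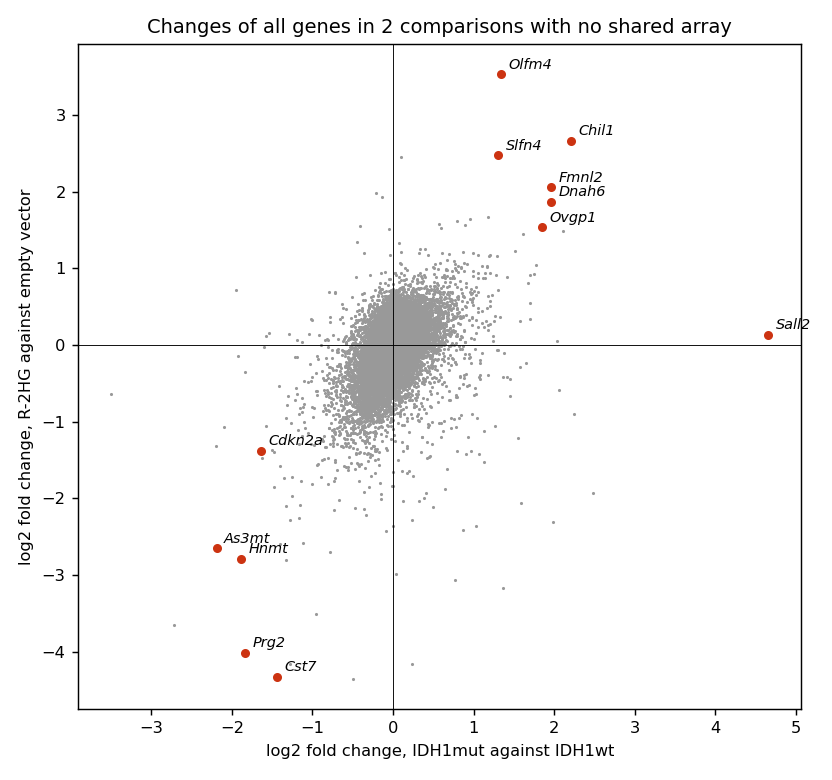
Log2 fold change of each gene in IDH1mut against IDH1wt (horizontal axis) and in R-2HG against empty vector (vertical axis), with 1 point per gene and 12 named genes in red. The changes correlate with r = 0.439, As3mt and Chil1 lie far out in both contrasts, and Sall2 changes in IDH1mut only.

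The difference between the 2 effects was tested directly, as IDH1mut against R-2HG. Growth, stem and progenitor, B cell and erythroid genes were higher in IDH1mut. Of 40 MYC and ribosome biogenesis genes 29 were higher and 0 lower (31 and 1 adjusted over the list alone), with a median of 0.47 and Nop56 at 0.85 ± 0.14. DNA replication and G1/S genes (21 higher, 2 lower of 38), mitosis and G2/M genes (17 higher, 0 lower of 36) and DNA methylation machinery genes (9 higher, 0 lower of 17) were higher too. Stem and progenitor genes (12 higher, 0 lower of 22) included Cd34 at 1.02 ± 0.13 and Mecom at 1.80 ± 0.13, the latter with the opposite sign at 1 probe set (-0.36, adjusted p = 0.098). B cell genes (12 higher, 0 lower of 19) and erythroid genes (15 higher, 0 lower of 18) had medians of 1.29 and 1.41, with Vpreb1 at 3.53 ± 0.44. With an estimated correlation the adjusted p of these 7 lists lay between 0.558 and 0.662. The erythroid list no longer passed without R-2HG replicates 1 and 2.

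Smaller shifts were found in TCA cycle, IDH and glutamate metabolism genes (13 higher, 0 lower of 34), cholesterol and fatty acid synthesis genes (12 higher, 1 lower of 27), hypoxia and HIF target genes (13 higher, 3 lower of 30), oxidative phosphorylation genes (8 higher, 0 lower of 33) and amino acid and ER stress genes (14 higher, 1 lower of 35). Primary granule genes were lower, 5 of 9, with Elane at -0.67 ± 0.13. With an estimated correlation the adjusted p of these 6 lists lay between 0.558 and 0.812. Of 21 other settings, the primary granule and oxidative phosphorylation lists lost their call in 5 each, the amino acid and ER stress list in 4 and the hypoxia list in 1. The secondary granule and type I interferon lists had medians of 0.02 and -0.02 and did not pass. Cdkn2a was lower in IDH1mut (-0.99 ± 0.21, adjusted p = 0.00478) and Olfm4 was lower as well (-1.36 ± 0.18).

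Limma called 5714 genes, 3212 higher and 2502 lower, of which 240 and 22 differed at least 2-fold. The groups did not overlap in 47.9% of all genes. Without R-2HG replicates 1 and 2 the calls of Elane (-0.36, adjusted p = 0.181) and Nop56 (0.43, adjusted p = 0.051) were lost with smaller changes, and that of Cdkn2a (-1.26, adjusted p = 0.0533) was lost although its change was not smaller. The count was 336 without these 2 arrays, 3376 without replicate 1, 3109 without replicate 2 and 1031 with a fold change of at least 1.5.

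**Figure D4:**
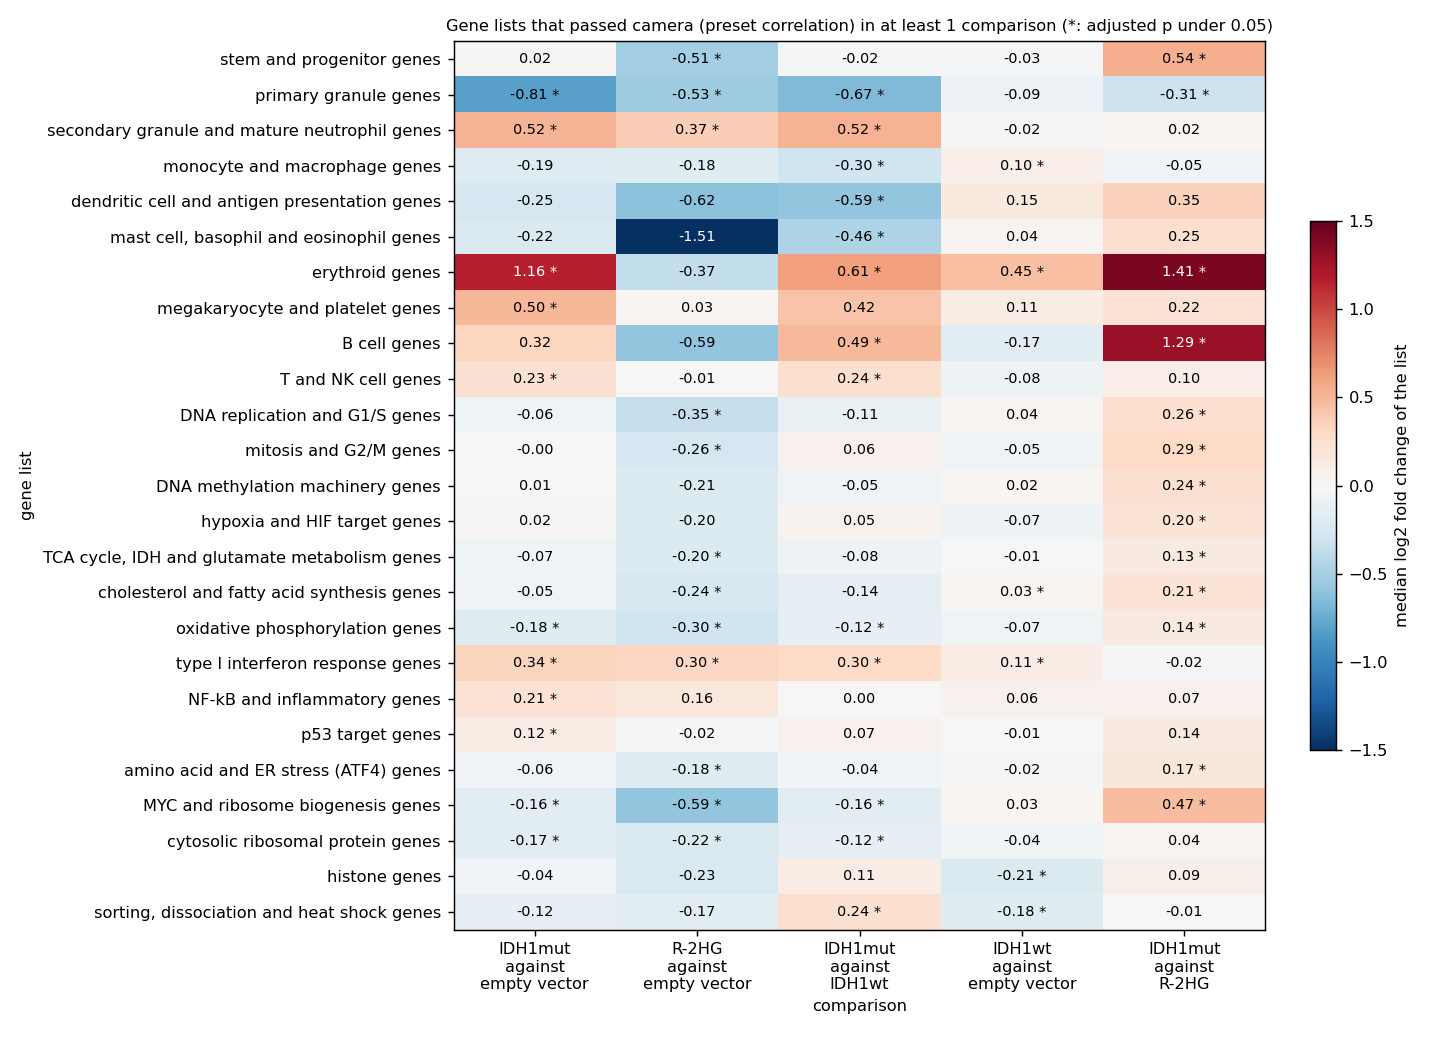
Median log2 fold change of each gene list (rows) in the 5 comparisons (columns), for lists that passed camera with a preset correlation in at least 1 comparison, with passing lists starred. The secondary granule list lies at 0.52, 0.37 and 0.52 and the primary granule list at -0.81, -0.53 and -0.67 in the first 3 columns.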

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

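Counts within 1.5 times the reported one, and named genes on the same side of the threshold, are taken as kept. Of the named gene values, 2739 were kept, 17 lost their call, 26 gained one and 39 changed sign, and of the summary values 244 were kept and 38 moved. Centring each array cannot change values whose array medians are all 0 and is left out of these tallies. The gene lists for secondary and primary granules kept their direction and call in all settings but the estimated correlation in the 3 comparisons of IDH1mut or R-2HG with a control. The filter on mean level was not run, since centred values carry no level. What signal over background limits could not be told from centred values. Where no reason is given below, the cause was not tested.

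With a fold change of at least 1.5 the counts were 930 (IDH1mut against empty vector), 1627 (R-2HG against empty vector), 596 (IDH1mut against IDH1wt), 119 (IDH1wt against empty vector) and 1031 (IDH1mut against R-2HG), since fewer genes can pass. With single probe sets, more tests in all, they were 6927, 12605, 4457, 741 and 10814, and 16748 for the F test. These count probe sets and not genes, so they cannot be set against the gene counts, although the tally of moved values holds them. With an estimated correlation 0 lists passed in each of the 5 comparisons, and by fry 5 in IDH1mut against IDH1wt and 3 in IDH1wt against empty vector. For IDH1wt against empty vector the count was 419 with a second quantile normalization, 1388 with array weights (44.4% higher, against 58.4%) and 382 with the probe set of the highest SD, and 10 lists passed in the fit of 6 arrays and 3 with the probe set of the highest mean. The similarity without shared arrays was 0.475 after quantile normalization and 0.398 with array weights, and that with shared controls 0.599 after quantile normalization. Without R-2HG replicates 1 and 2 together, which leaves 1 array assumed to vary like the other groups, the counts were 1824 for R-2HG against empty vector and 336 for IDH1mut against R-2HG. That setting, the probe sets with the highest mean and SD and the SD filter were chosen after seeing the data.

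With each array left out in turn the counts ran from 2427 to 4107 (IDH1mut against empty vector), 4588 to 7018 (R-2HG against empty vector), 1568 to 2977 (IDH1mut against IDH1wt), 84 to 375 (IDH1wt against empty vector), 3109 to 6503 (IDH1mut against R-2HG) and 6372 to 9049 (F test). The lists that passed ran from 11 to 12, 11 to 17, 10 to 16, 3 to 9 and 9 to 15 in the same order, and the similarities from 0.402 to 0.45 and from 0.436 to 0.551. Arrays that moved a count more than 1.5 times were empty vector replicates 2 (89) and 3 (84), IDH1wt replicates 2 (123) and 3 (86, with 3 lists) and R-2HG replicate 3 (375) for IDH1wt against empty vector, IDH1wt replicate 3 (1568) and IDH1mut replicate 2 (1636) for IDH1mut against IDH1wt, and R-2HG replicates 1 (3376) and 2 (3109) for IDH1mut against R-2HG. In IDH1wt against empty vector, R-2HG replicate 3 acts only through the estimate of spread shared by all arrays.

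With a replicate block the counts were 3258, 6183, 2178, 147 and 5346, and the histone list in IDH1wt against empty vector was lost. Same-numbered arrays of different groups correlated at -0.15 to 0.12 once group means were taken off, other pairs at -0.18 to 0.17, so the numbers do not pair the arrays.

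Of the genes that changed sign, Mecom in IDH1mut against R-2HG ended furthest from 0 (-0.36 at 1 probe set), followed by Dnmt3a. Against empty vector in IDH1mut, single probe sets gave Cdkn1a 0.097, D2hgdh -0.027, Dnmt3a 0.319, 0.091 and 0.065 and Mllt3 -0.115 and -0.044. In IDH1mut against IDH1wt they gave Cdkn1a -0.021 and D2hgdh 0.073, and in IDH1mut against R-2HG Cdkn1a 0.188 and D2hgdh -0.008. The probe set with the highest mean gave Cdkn1a 0.097 and 0.188, Dnmt3a 0.091, Mllt3 -0.044 and D2hgdh 0.073, and that with the highest SD Mllt3 -0.044, Cdkn1a -0.021 and D2hgdh 0.073. Array weights gave Cdkn2b -0.023, -0.024 and 0.001 and Tet2 -0.004. Without R-2HG replicates 1 and 2 Idh1 was at -0.116 and 0.055. With each array left out in turn, Cdkn2b ran from -0.061 to 0.106 (IDH1mut against empty vector), -0.047 to 0.234 (R-2HG against empty vector) and -0.21 to 0.072 (IDH1mut against R-2HG), and D2hgdh from -0.034 to 0.135 (IDH1mut against empty vector) and -0.121 to 0.048 (IDH1mut against IDH1wt). For IDH1mut against empty vector Dnmt3a ran from -0.091 to 0.021, Mllt3 from -0.011 to 0.102 and Tet2 from -0.038 to 0.157, and for IDH1mut against R-2HG Cdkn1a from -0.141 to 0.041.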

Other observations

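All tests of explanations in this part were chosen only after the results were seen. Hoxb3, Hoxb4 and Mllt3 lie outside the naming rule and were chosen after their values were seen, as were the groupings of the genes in the first paragraphs, which no fixed list tests.

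A few genes tied to blood stem cells were higher in the R-2HG arrays than in empty vector arrays, while the fixed stem and progenitor list fell (11 lower and 1 higher of 22, median -0.51). Hoxb3 changed by 1.34 ± 0.12 (adjusted p = 4.99e-05), Hoxb4 by 0.82 ± 0.10, Mllt3 by 1.22 ± 0.14 and Prdm16 by 1.56 ± 0.31, the last not called without R-2HG replicates 1 and 2 (0.60, adjusted p = 0.0959) or at 1 probe set (0.29, adjusted p = 0.104). In IDH1mut the same genes stood at 0.23 ± 0.12, 0.03 ± 0.10, 0.06 ± 0.14 and -0.70 ± 0.31 and did not pass, but Prdm16 passed as a decrease with array weights (-0.76, adjusted p = 0.0175), in the fit of 6 arrays (adjusted p = 0.00481) and without R-2HG replicate 3 (adjusted p = 0.00432), and Hoxb3 as an increase without empty vector replicate 1 (0.37, adjusted p = 0.0303).

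The serine synthesis genes Phgdh, Psat1 and Psph fell in R-2HG by 0.85 ± 0.10, 1.09 ± 0.16 and 0.87 ± 0.09 on the log2 scale. They belong to the amino acid and ER stress list, whose adjusted p was 0.0396, or 0.659 with an estimated correlation.

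The eosinophil granule genes Prg3 and Epx were lower in both IDH1mut and R-2HG, while the mast cell, basophil and eosinophil list passed in neither (adjusted p = 0.554 and 0.22). Prg3 changed by -1.23 ± 0.19 and -1.29 ± 0.19 against empty vector and Epx by -1.10 ± 0.30 and -1.73 ± 0.30. The call of Epx was lost, with changes nearly as large, in IDH1mut without empty vector replicate 2 (-0.91, adjusted p = 0.0793) or 3 (-0.98, adjusted p = 0.0736) or IDH1mut replicate 3 (-1.08, adjusted p = 0.0585), and in R-2HG without R-2HG replicates 1 and 2 (-1.32, adjusted p = 0.0636). Prg2 stood at -4.12, -4.16 and -0.28 in R-2HG replicates 1, 2 and 3 and between -0.99 and -0.64 in the IDH1mut arrays. Siglecf changed by -2.09 ± 0.41 in R-2HG and by -0.86 ± 0.41 in IDH1mut, where it did not pass but did after quantile normalization (-1.19, adjusted p = 0.00033), with array weights (-0.94, adjusted p = 0.0231), in the fit of 6 arrays (adjusted p = 0.00556) and without R-2HG replicate 3 (adjusted p = 0.000801).

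On the first principal component R-2HG replicate 3 lies between R-2HG replicates 1 and 2 and the other arrays. A swap with an array of another group is argued against. The lowest correlation of replicate 3 with its own group exceeds its highest with any other array by 0.447. Not all list medians lay between. In R-2HG replicates 1, 2 and 3 that of MYC and ribosome biogenesis genes was -0.584, -0.564 and -0.209, nearer empty vector in replicate 3. That of interferon genes was 0.006, 0.031 and 0.295, and that of primary granule genes -0.303, -0.227 and -0.364. In both, replicate 3 lay further from empty vector. For primary granule genes replicate 3 lay no further from replicate 1 than replicate 2 did, and the IDH1mut arrays lay lower still (-0.567 to -0.498). That median thus leaves both a mixture and a smaller change open. For interferon genes replicate 3 lay above every IDH1mut array (0.106 to 0.256), where neither explanation would place it, but this rests on 1 array. Whether replicate 3 may hold a mixture of cells, or the same change at a smaller size, cannot be told apart, because the answer turned with the cutoff used to pick genes. The cutoff planned was 2, the first one run was 1.5, and 6 combinations with a second cutoff were run in the end. With genes changed by at least 1 in replicates 1 and 2 (17 higher, 175 lower), the linear share differed between higher and lower genes by -0.193 (95% interval -0.284 to -0.071), against a mixture, and the log2 ratio by 0.063 (-0.09 to 0.145). At cutoffs of 1.5 and 2 the verdicts were the opposite, but on few higher genes. The log2 ratio differed by 0.204 and 0.316 on 3 and 1 higher genes, or by 0.212 and 0.254 on 6 and 3 with the wider second cutoff. The linear share differed by -0.06 and -0.013, or by -0.13 and -0.049 with the wider one, and all these intervals included 0. So few higher genes cannot tell a mixture from a loss of power.

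Heat shock and immediate early genes are high in the empty vector arrays, Hspa1a by 4.12 and Jun by 1.49 over the mean of the 9 other arrays. A handling or heat response in those cells may be the cause. The mean of 5 other chaperone genes was higher by 0.159, but this was within their spread (exact two-sided permutation p = 0.3136), so the question stays open. The 5 genes ran from -0.022 (Dnaja1) to 0.37 (Hspa8). For Hspa8 all 3 empty vector arrays lay above every other array. That the empty vector arrays alone set the neutrophil granule shift is argued against, since the secondary granule list had a median of 0.521 against IDH1wt. The R-2HG cells carried the same vector per most labels, and Hspa1a was lower there too (-3.06 ± 0.32, adjusted p = 7.26e-05), as was Ptprg (-2.99 ± 0.16).

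The IDH1mut and R-2HG arrays share changes against the IDH1wt and empty vector arrays. In 740 genes the 6 arrays of the first 2 groups lay beyond all 6 others with means at least 0.5 apart, compared with 85 genes for the IDH1 constructs against both empty vector groups and 22 for the remaining pairing. A difference between arrays in how their centred values are distributed is argued against, since quantile normalization of those values left the correlation at 0.475. A difference in the distribution of absolute levels cannot be tested, since centred values carry no level. Exposure to 2-hydroxyglutarate is the explanation the design names, as a hypothesis, but array batches aligned with the groups could give the same 740 genes and cannot be told apart from it, because no batch is given.

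Other splits of the arrays were counted for each comparison. The 10 splits of 6 arrays are too few for a share under 0.05, and only 1, the real one, gave as many genes in each comparison. The real and highest other counts were 3579 and 0 for IDH1mut against empty vector, 6471 and 0 for R-2HG against empty vector, 2484 and 0 for IDH1mut against IDH1wt, 214 and 1 for IDH1wt against empty vector, and 5714 and 6 for IDH1mut against R-2HG. For the F test over the 4 groups 1 of 100 splits, the real one, gave as many as 8651 genes, and the highest other gave 1960. That is the smallest share these splits allow. The other splits also mix groups that differ, which widens their spread, so chance is made less likely there but is not excluded.

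Ptprg was high in the empty vector arrays, with a mean of 3.00 ± 0.42 (SD, n = 3), and at 0.01 ± 0.05 in the R-2HG arrays, whose cells carried the same vector per most labels.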
